A study of Arabidopsis thaliana with 6 samples.

How the data were processed

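The series holds 6 Affymetrix arrays of RNA from Arabidopsis trichomes, 3 from wild type and 3 from the gtl1-1 mutant. Per the labels' protocols, plants grew on sugar-containing plates in continuous light, trichomes were taken with forceps from rosette leaves of plants aged 3 weeks, and RNA was labelled with a kit that primes from the 3′ end of transcripts. Groups and replicate numbers were taken from the labels, which describe the 3 samples of each genotype as biological replicates. The authors deposited 1 table of log2 expression values, made with GCRMA per the submitters' processing notes, which corrects the background by probe sequence, normalises by quantiles and summarises the probes of each set. Its version is not given in the sources used here. That the values are log2 follows from their range, 2.14 to 15.5, as no header or label states the scale. GCRMA compresses dim probe sets onto a floor. Between 23.0% and 24.3% of the probe sets of an array lay at the lowest value, so changes of dim genes are bounded by it and have little spread there.

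The table held 22810 probe sets. The 64 Affymetrix control probe sets were left out of the tests, and the values were not normalised again. A probe set was tested if it lay above the 40th percentile of its own array in at least 3 of the 6 arrays, which left 13682. Probe sets were named through the platform annotation and a gene table of the reference assembly, used for names and gene order only. In that annotation 13513 probe sets name 1 gene, 503 name several and 8730 are unnamed here, and among those tested the numbers are 7467, 286 and 5929. No gene was named from a probe set with several genes. No coordinates are given because the sources used here do not name the build behind the array. The annotation assigned 0 probe sets to GTL1 and 0 to FZR2 (CCS52A1), so these planned results were not analysed here, and the mutant label could not be checked on the mutated gene.

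Each probe set was fitted by genotype with limma 3.58.1 (lmFit and eBayes, default settings) in R 4.3.3, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05. All limma tests and permutation tests are two-sided, except the test of neighbouring called genes, which is one-sided (more neighbours than in random draws). Log2 changes are mutant minus wild type. Gene lists were tested with limma's camera at the preset correlation of 0.01 between genes, with the brightest probe set of each gene, for lists of at least 5 tested members. Camera compares a list with the other probe sets, and it was repeated with an estimated correlation. Fry tests whether the members move, on balance, in one direction, and does not compare them with other genes. No list passed any of these 3 tests in the main setting. Single values per array were compared by exact permutation of the 6 arrays, which cannot give a p under 0.1. The test was tried on data simulated for the comparison of mutant with wild type, with 13682 probe sets of which 200 were changed. It recovered 67.2% of the changes of 1 log2 unit, 98.5% of those of 2 and 100% of those of 3, with 14 false calls (7.33% of the calls). The simulated noise was normal and independent between probe sets, with the variances of the fit. It held no differences shared by the probe sets of an array, so these rates may not hold for the real data.

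The design, the filter, the thresholds, the gene lists, the alternatives (other than those named as added) and the rule for named genes were fixed before the data were examined. The rule took GTL1 and CCS52A1, the 10 called probe sets with the largest change in each direction that name 1 gene and whose genotypes do not overlap, and from each list up to 4 members with the smallest p. The unnamed probe sets given by identifier, and listed genes beyond those 4, were added after their values were seen. Listed genes were matched by locus. Of the listed entries, 3 have a reference symbol of another form (BDG, EXPA3 and HSP22.0, none of them tested) and 14 have no symbol in the reference.

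The 2 genotypes share replicate numbers, and the labels do not say whether a number marks a shared batch. The deviations of the arrays from their genotype means correlated at 0.127, 0.275 and 0.118 between the arrays numbered 1, 2 and 3, and each array correlated best with the one of its own number. Every value was over 0.1, so the numbers were taken to pair the arrays, from the data alone. That evidence is weak, as wild type replicate 3 and gtl1-1 mutant replicate 1 also correlated at 0.087. The main count does not use the pairing, and the count of calls with the replicate number as a block is given beside it. The alternatives were no filter, a filter at the 60th percentile, another quantile normalisation, a common median, a variance trend with robust estimation, array weights, the replicate block, leaving out each array, other thresholds, a floor at the 20th percentile, other tests of the lists and the mean of a gene's probe sets. The 25S ribosomal RNA value of each array as a covariate was added after the data were seen, as were camera with an estimated correlation in that fit and in the fit without wild type replicate 3.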

Results

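Transcript levels were measured in leaf trichomes, the hairs that each grow from one epidermal cell of the Arabidopsis leaf, in wild-type plants and in the gtl1-1 mutant. GTL1 is a trihelix transcription factor known to hold back the late growth of trichomes and their endoreduplication, the copying of nuclear DNA without cell division. Trichomes had been collected with forceps from rosette leaves of plants aged 3 weeks, and RNA from 3 biological replicates of each genotype was hybridised to Affymetrix arrays, which gave 6 arrays. The comparison asks which transcripts differ between mutant and wild-type trichomes. The deposited values were log2 expression estimates between 2.14 and 15.5, with array medians between 5.48 and 5.57. Arrays have no sequencing depth, and their number, 3 per genotype, limits the precision of every value. Arrays of the same genotype correlated across probe sets at Pearson's r between 0.992 and 0.996, and arrays of different genotypes at r between 0.989 and 0.993. The first principal component held 40.3% of the variance and separated the genotypes, with scores from -27.0 to -21.4 in wild type and from 19.3 to 26.4 in the mutant. The annotation used here assigned 0 probe sets to GTL1, so the level of the mutated gene was not analysed here and the genotypes rest on the labels alone.

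The genes that were higher in gtl1-1 trichomes included a putative wall protein, a pectate lyase, a lipase and a mannosidase. AT2G20870, annotated as a putative cell wall protein precursor, rose from 9.21 ± 0.44 to 12.67 ± 0.19 on the log2 scale (mean ± SD, n = 3 per genotype), an 11-fold difference. AT4G13210, a member of the pectate lyase family, whose enzymes cut pectin, rose from 8.14 ± 0.44 to 11.38 ± 0.29, a 9.48-fold difference. AT2G42990, a GDSL-type esterase or lipase, rose 7.87-fold, with a log2 change of 2.98 ± 0.40 (SE), but was not called with the replicate number as a block (limma adjusted p = 0.0665). AT5G66150, an alpha-mannosidase of the glycosyl hydrolase class, rose 11.1-fold, from 3.13 ± 0.52 to 6.61 ± 0.09 (mean ± SD, n = 3 per genotype). The wild-type mean of AT5G66150 lay below the 40th percentile of every array (at least 3.51), where background correction compresses values towards the floor of 2.14, so the size of its rise is limited by that.

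Of the called genes with a name, AT3G18250 had the largest measured rise in the main fit, at 4.26 ± 0.59 (log2 change ± SE, n = 3 per genotype) or 19.1-fold, with a limma adjusted p of 0.0299. With the replicate number as a block, AT3G18250 was not called (limma adjusted p = 0.0513). AT5G53710 rose by 3.92 ± 0.25 (adjusted p = 0.0018) and AT3G56060, of the glucose-methanol-choline oxidoreductase family, by 3.82 ± 0.20 (adjusted p = 0.000507), both in limma. Without wild type replicate 1 the order of AT3G18250 (3.84) and AT5G53710 (3.89) turned, and AT5G53710, at 2.74 ± 0.05 in wild type (mean ± SD, n = 3), was itself close to the floor of 2.14. AT2G19970, of the superfamily that holds the pathogenesis-related PR-1 proteins, rose by 3.36 ± 0.16 (limma adjusted p = 0.000466). AT3G59480, a kinase of the fructokinase family, rose by 3.5 ± 0.38 (limma adjusted p = 0.0124). AT2G19970 and AT3G59480 lay within 0.5 log2 units of the lowest value of the data in wild type, so the size of their change is limited by that floor. AT2G19970 read 2.30 on each of the 3 wild-type arrays, so its small p also rests on values without spread. AT2G41810 rose by 3.09 ± 0.44 (limma adjusted p = 0.0331), with the same limit as AT5G66150 in wild type. It was not called with the replicate number as a block (limma adjusted p = 0.0768). Over the 10 genes with the largest rises, the limma adjusted p in the main fit ranged from 0.000466 to 0.0331. Among probe sets that the annotation leaves unnamed, 262595_at rose by 3.37 and 267032_at by 3.29, the latter also within 0.5 log2 units of the floor in wild type.

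The genes that were lower in gtl1-1 trichomes included a calmodulin-binding protein, a cold-regulated protein and a sugar porter. IQD15 (AT3G49380), of a family of calmodulin-binding proteins with an IQ domain, fell by 3.1 ± 0.27 (log2 change ± SE, n = 3 per genotype), an 8.60-fold difference, with a limma adjusted p of 0.00375. COR15A, a cold-regulated protein of the chloroplast stroma, went from 6.09 ± 0.51 in wild type to 3.3 ± 0.65 in the mutant (mean ± SD), 6.90-fold lower, a size that is also limited, as its mutant mean lay below the 40th percentile of every array. COR15A was not called with the replicate number as a block (limma adjusted p = 0.0743). SFP1, of the sugar-porter family, went from 10.33 ± 0.42 to 7.72 ± 0.36, 6.10-fold lower. NCRK, a receptor-like kinase, fell by 1.42 ± 0.15 (SE), and AGL59, a MADS-box transcription factor, fell by 2.14 ± 0.33 (SE). The AGL59 probe set is of a type that can also bind related transcripts.

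The largest measured fall of a named gene in the main fit was that of AT3G48970, which encodes a protein with a heavy-metal-associated domain and fell by 3.71 ± 0.27 (log2 change ± SE, n = 3 per genotype, limma adjusted p = 0.0021). AT5G59080 fell by 3.28 ± 0.23 (limma adjusted p = 0.00189) and AT1G16705 by 2.03 ± 0.17 (limma adjusted p = 0.00347). AT3G48970 and AT1G16705 lay within 0.5 log2 units of the floor in the mutant, so the sizes of their falls are limited by it. AT1G75900, a GDSL-type extracellular lipase, fell by 1.84 ± 0.20 (SE), from 9.85 ± 0.24 to 8.01 ± 0.30 (mean ± SD). AT4G09760, of the choline kinase family, fell by 1.55 ± 0.25 (limma adjusted p = 0.049), and over the 10 genes with the largest falls the adjusted p ranged from 0.00189 to 0.049. Among these named genes, the GDSL-type AT2G42990 was thus higher and AT1G75900 lower, and a shift of that family was not tested. AT2G42990 kept its call in 1 and AT1G75900 in 3 of the 6 fits that left out an array. The largest change of any tested probe set was a fall of the unnamed 261594_at, at -6.42 (limma adjusted p = 7.33e-05), whose mutant mean also lay below the 40th percentile of every array, and the unnamed 262113_at fell by 4.1.

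**Figure D1:**
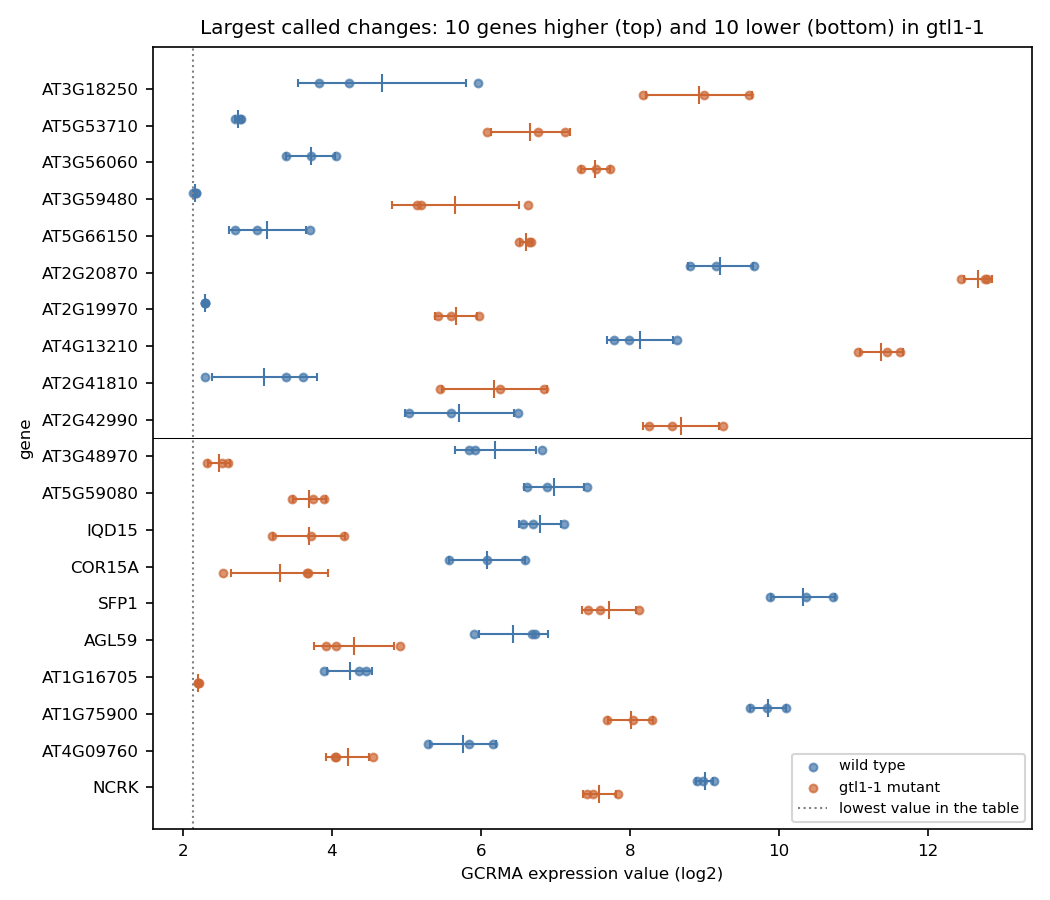
GCRMA expression values (log2, horizontal axis) of the 20 named genes with the largest called changes in the 3 wild-type and 3 gtl1-1 arrays; dots are arrays, vertical ticks are means, bars are 1 SD and the dotted line is the lowest value of the data, 2.14. The mutant and wild-type dots of each gene do not overlap, as the rule for naming these genes requires. AT3G59480 and AT2G19970 in wild type and AT3G48970 and AT1G16705 in the mutant lie close to the dotted line.

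Across the array, 126 of 13682 tested probe sets (0.921%) had a limma adjusted p under 0.05, of which 81 were higher and 45 lower in the mutant. Of these 126, 58 named 1 gene (42 higher, 16 lower), 5 named several genes and 63 were unnamed. The change was at least 2-fold for 100 probe sets and at least 8-fold for 17, and the median size was 2.49-fold among those higher and 2.92-fold among those lower. The 3 mutant and 3 wild-type values did not overlap at any of the 126, which a call with 3 arrays per genotype nearly requires. They did not overlap at 20.9% of all tested probe sets, where chance gives 10%. An unadjusted p under 0.05 was reached by 2045 probe sets (1067 higher, 978 lower). With the replicate number as a block, the count was 68 (42 higher, 26 lower; 56 of them among the 126), and AT3G18250, AT2G41810, AT2G42990 and COR15A were no longer called (limma adjusted p = 0.0513, 0.0768, 0.0665 and 0.0743). The count was 36, 39 or 81 without wild type replicate 1, 2 or 3, 65, 38 or 31 without gtl1-1 mutant replicate 1, 2 or 3, and 8 with no filter on dim probe sets. With 1 array left out, the share of calls higher in the mutant ran from 52.3% (without gtl1-1 mutant replicate 1) to 74.2% (without gtl1-1 mutant replicate 3). AT5G53710, AT3G56060, AT5G66150, AT2G20870, AT2G19970, AT4G13210, AT3G48970, AT5G59080, IQD15 and AT1G16705 kept an adjusted p under 0.05 in each of the 6 fits that left out an array. AT2G41810 and AT4G09760 kept it in 0 of those 6 fits, AT3G18250, AT2G42990 and AGL59 in 1, COR15A and NCRK in 2, SFP1 and AT1G75900 in 3, and AT3G59480 in 4.

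**Figure D2:**
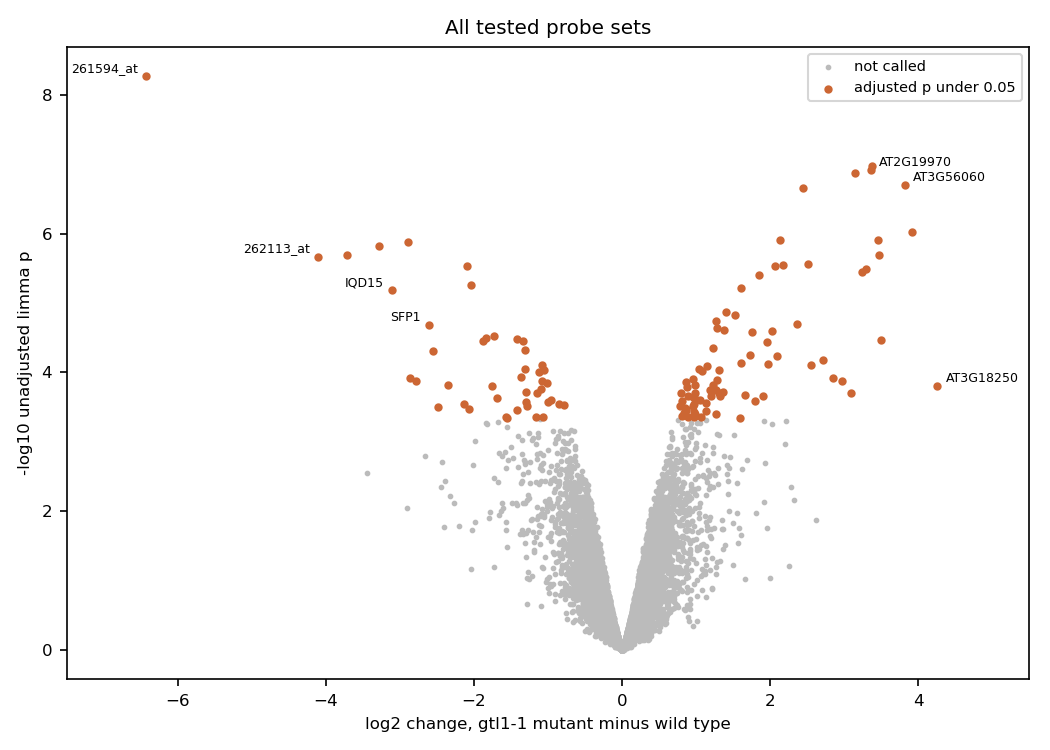
Log2 change (gtl1-1 mutant minus wild type, horizontal axis) against -log10 of the unadjusted limma p (vertical axis) for the 13682 tested probe sets; grey dots are probe sets not called and orange dots are the 126 with an adjusted p under 0.05, some of them labelled. The 81 orange dots on the right and 45 on the left all lie outside the dense centre, and 261594_at stands farthest to the left at -6.42.

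Named pathways were followed in 21 gene lists. Of their 484 loci, 72 had a probe set that named them alone and 55 passed the filter, so most lists were seen through a few members. Over all probe sets, limma called 0 of the 55 listed genes, and 13 had an unadjusted p under 0.05. Among all tested probe sets, 0.921% were called and 14.9% had an unadjusted p under 0.05. At so low a share of calls, 0 among 55 genes does not show that these pathways were unchanged. With the filter at the 60th percentile, RTE1 was called (limma adjusted p = 0.0478, against 0.0697 in the main fit). Adjusted over the list alone, 6 listed genes had a limma adjusted p under 0.05. These were GIS and TUB6, higher in the mutant, and RTE1, GH3.5, IAA18 and LHCB4.2, lower in the mutant. The adjustment over a list alone covers few genes and does not account for the number of lists. The tested members were 3 in the list of GIS, 7 in that of TUB6 and 5 in that of LHCB4.2. They were 2 in the list of RTE1 and 2 in that of GH3.5 and IAA18.

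Among regulators of trichome fate, GIS, a zinc finger protein that promotes trichome initiation, had a log2 change of 0.84 ± 0.20 (SE, n = 3 per genotype; limma p adjusted over the list alone 0.0118), from 5.39 ± 0.09 to 6.23 ± 0.38 (mean ± SD). TRY, a small MYB protein that represses trichome formation in neighbouring cells, had a change of -0.99 ± 0.50, and AN, which shapes trichome branching, one of 0.12 ± 0.14, neither of them called, and TRY stood at -0.57 without gtl1-1 mutant replicate 2. Of the genes that shape trichomes through actin and microtubules, 7 were tested, 5 with positive and 2 with negative changes and a mean of 0.15. The beta-tubulin gene TUB6 had a change of 0.50 ± 0.13 (limma p adjusted over the list alone 0.0379), TUA6 one of 0.34 ± 0.16, the tubulin-folding cofactor TFCC one of 0.36 ± 0.14 and ARPC5, of the actin-nucleating ARP2/3 complex, one of -0.24 ± 0.20. The list as a whole did not pass camera (adjusted p = 0.142; adjusted p = 0.521 with an estimated correlation), nor fry (adjusted p = 0.204).

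The cell wall list had 8 tested members with a mean change of -0.37, of which 3 were positive and 5 negative and 0 were called by limma (3 at an unadjusted p under 0.05). XTH18 and XTH16, enzymes that cut and rejoin xyloglucan, had the most negative changes, at -1.56 ± 0.51 and -0.86 ± 0.34 (log2 ± SE, n = 3 per genotype), and XTH18 stood at -0.93 without gtl1-1 mutant replicate 1. XTH27 stood at -0.33 ± 0.17, and TBR, needed for cellulose deposition in trichome walls, at 0.34 ± 0.13. The list did not pass camera (adjusted p = 0.142; adjusted p = 0.476 with an estimated correlation) or fry (adjusted p = 0.204). Without wild type replicate 3 its mean was -0.52 with a camera adjusted p of 0.0409 (adjusted p = 0.32 with an estimated correlation), and over all alternatives the adjusted p ranged from 0.0409 to 0.557.

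Cell cycle genes were represented by few members. In the endocycle list, SIM, an inhibitor of cyclin-dependent kinases whose loss lets trichomes divide, stood at 11.67 ± 0.16 in wild type and 11.79 ± 0.44 in the mutant (mean ± SD, n = 3 per genotype), a change of 0.12 ± 0.23 (SE). HBT, a subunit of the anaphase-promoting complex, had a change of -0.12 ± 0.15. The mitotic Aurora kinases AUR1 and AUR2 had changes of -0.48 ± 0.31 and -0.59 ± 0.23, the replication helicase subunit MCM7 one of -0.09 ± 0.28 and the DNA ligase LIG4 one of 0.12 ± 0.13. None of these 6 genes was called by limma, over all probe sets or over its list alone, and AUR2 had an unadjusted limma p under 0.05. The annotation assigned 0 probe sets to CCS52A1 (FZR2), an activator of the anaphase-promoting complex, and its level was not analysed here.

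In the hormone lists, RTE1, which acts with the ethylene receptor ETR1, had a change of -0.87 ± 0.16 (log2 ± SE, n = 3 per genotype; limma p adjusted over the list alone 0.00164, over all probe sets 0.0697, with a range from 0.0478 to 0.242 over the alternatives), and EIN3 one of 0.06 ± 0.23. The auxin-conjugating enzyme GH3.5 stood at -1.10 ± 0.35 and the auxin repressor IAA18 at -0.44 ± 0.13, both with a limma p adjusted over the list alone of 0.016. The ethylene and auxin lists had 2 tested members each, so the adjustment over the list alone covers little there. The gibberellin receptors GID1A, GID1B and GID1C had changes of 0.47 ± 0.23, 0.34 ± 0.17 and 0.25 ± 0.20, and the repressor SPY one of 0.26 ± 0.18. All 4 tested gibberellin genes were positive and limma called 0 of them, with 0 at an unadjusted p under 0.05. In the jasmonate list, the defensin gene PDF1.2 had a change of 0.97 ± 1.2 (0.00049 without wild type replicate 1 and 2.09 without wild type replicate 3) and OPCL1 one of 0.23 ± 0.36. The salicylate and pathogen defence genes GRX480, SAG101 and WRKY53 stood at 0.75 ± 0.46, -0.30 ± 0.29 and -0.15 ± 0.26, and ZAT10, an early stress-response factor, at 0.25 ± 0.19. None of these defence and stress genes was called by limma, and 0 had an unadjusted p under 0.05.

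Among trihelix factors, the family of GTL1 itself, DF1 had a change of 0.55 ± 0.23 (log2 ± SE, n = 3 per genotype), GT2 one of 0.33 ± 0.24, GT-1 one of 0.02 ± 0.12 and GT-4 one of -0.50 ± 0.25. Limma called 0 of these 4, and DF1 had an unadjusted p under 0.05. In the lists for surface lipids and secondary metabolites, the wax ester synthase WSD1 stood at -0.02 ± 0.43 (0.012 with the arrays shifted to a common median), the flavonol glycosyltransferases UGT78D1 and UGT78D2 at -0.16 ± 0.23 and -0.09 ± 0.17, and the glucosinolate glycosyltransferases UGT74B1 and UGT74C1 at -0.03 ± 0.20 and -0.20 ± 0.20. None of these 5 was called by limma, and 0 had an unadjusted p under 0.05. No member of the heat shock list passed the filter.

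Markers of other leaf cell types that forceps could carry along were also read. Of 5 photosynthesis markers, the light-harvesting genes LHCB4.2 and LHCB4.1 had changes of -0.99 ± 0.26 (log2 ± SE, n = 3 per genotype; limma p adjusted over the list alone 0.0328) and -0.39 ± 0.15, while the Calvin cycle genes RCA, SBPASE and PRK stood at 0.01 ± 0.18, 0.03 ± 0.24 and 0.05 ± 0.22. Their mean change was -0.26 and their median 0.01, which differ in sign. The list did not pass camera (adjusted p = 0.164; adjusted p = 0.521 with an estimated correlation) or fry (adjusted p = 0.415). Without wild type replicate 3 its mean was -0.43 with a camera adjusted p of 0.0409 (adjusted p = 0.376 with an estimated correlation), and over all alternatives the adjusted p ranged from 0.0409 to 0.841. The mean signal of these 5 markers was 12.29 in wild type and 12.04 in the mutant. The stomatal lineage factors SPCH and FMA had changes of -0.55 ± 0.27 and 0.21 ± 0.33, and the phloem sugar transporter SWEET11 one of 0.54 ± 0.36, none of them called by limma and 0 at an unadjusted p under 0.05.

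**Figure D3:**
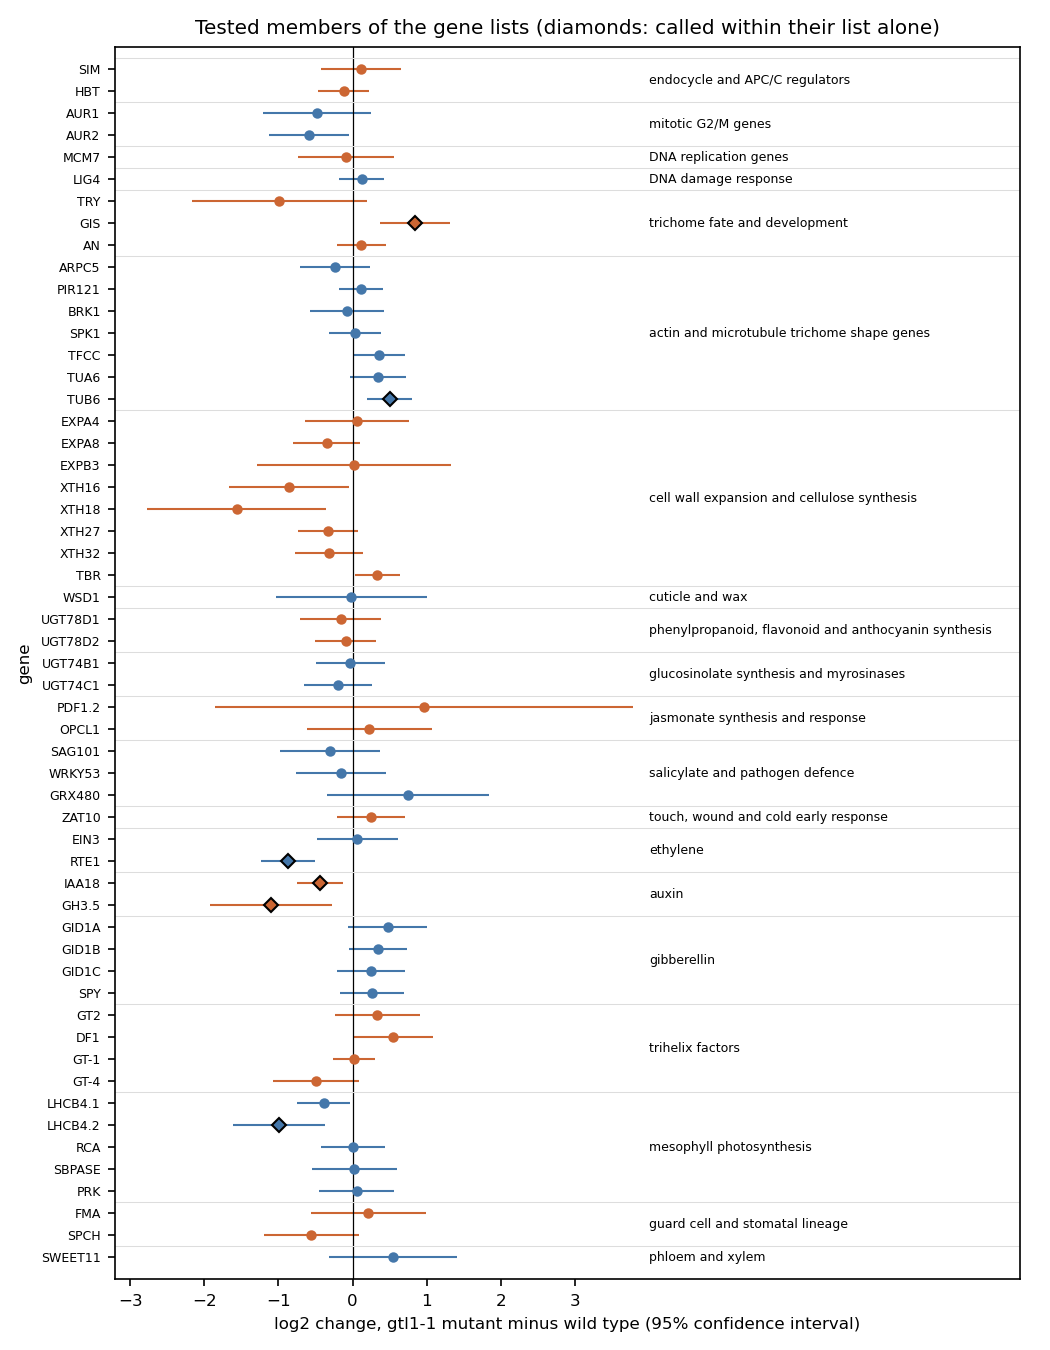
Log2 change (gtl1-1 mutant minus wild type, horizontal axis) of the 55 tested members of the gene lists, with list names on the right; points are limma estimates, bars are 95% confidence intervals, colours alternate between lists and diamonds mark genes with an adjusted p under 0.05 over their list alone. The 6 diamonds are GIS and TUB6 to the right of 0 and RTE1, IAA18, GH3.5 and LHCB4.2 to the left.

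Plastid transcripts and ribosomal RNA differed between genotypes by less than their spread between arrays of a genotype. The control probe set for 25S ribosomal RNA read 10.41 ± 1.90 in wild type and 11.24 ± 0.96 in the mutant (log2, mean ± SD, n = 3 per genotype; two-sided exact permutation p = 0.7, where 0.1 is the smallest possible), and its lowest value, 8.45, was in wild type replicate 3. The median of 60 plastid-encoded probe sets was 9.20 ± 0.67 in wild type and 9.33 ± 0.25 in the mutant (n = 3 per genotype, exact permutation p = 0.8). Across the 6 arrays, the 25S value rose with the plastid median (Pearson's r = 0.962, exact permutation p = 0.00278, adjusted 0.00833; Spearman's rho = 0.943, exact permutation p = 0.0167, adjusted 0.025). It fell with the second principal component, which held 23.7% of the variance (r = -0.892, exact permutation p = 0.00694, adjusted 0.0104; rho = -0.943, exact permutation p = 0.0167, adjusted 0.025). No pooled value is given for its relation to the first component, because that component parts the arrays into the genotypes, and 3 arrays each are too few for a value per genotype. The adjustment was over 3 relations, that one included. These permutations treat the 6 arrays as independent and ignore genotype and replicate number, so their p values may be too small. Without the pair of arrays farthest from the median 25S value, r was 0.828 with the plastid median and -0.72 with the second component. The difference between the 3′ and 5′ probe sets of the GAPDH control, a sign of RNA integrity, was 1.82 ± 0.27 in wild type and 1.65 ± 0.20 in the mutant (n = 3 per genotype, exact permutation p = 0.5). The difference between the 3′ and middle probe sets of the actin control was 0.24 ± 0.09 in wild type and -0.01 ± 0.19 in the mutant, a gap of -0.25 that is larger than either SD (n = 3 per genotype, exact permutation p = 0.3). For the ubiquitin control the 3′ to 5′ difference was 0.73 ± 0.05 and 0.78 ± 0.08 (n = 3 per genotype, exact permutation p = 0.5).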

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

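The fits with the 25S value as a covariate, and the estimated correlations in them and without wild type replicate 3, were chosen after the data were seen. The 20 named genes and 4 unnamed probe sets with the largest changes kept their direction in each fit that tested them, and AT2G19970, 262595_at and 261594_at kept an adjusted p under 0.05 in each of those fits. Of these 24, limma called 24 with another quantile normalisation, a common median, a variance trend or array weights, 22 with the 25S covariate, 20 with the replicate block and 3 with no filter, and the filter at the 60th percentile tested 11 and called 11. Without wild type replicate 1, 2 or 3 it called 14, 15 or 21 of them, and without gtl1-1 mutant replicate 1, 2 or 3 it called 20, 16 or 15. The count of 126 called probe sets was 113 at the 60th percentile filter, 141 with another quantile normalisation, 132 with a common median, 149 with a variance trend, 178 with array weights and 124 with the 25S covariate (85 of them among the 126). It was 68 with the replicate block, 31 to 81 when 1 array was left out, 29 at an adjusted p under 0.01, 228 at an adjusted p under 0.1, 100 when a 2-fold change was also required and 918 at an unadjusted p under 0.05 with a 1.5-fold change. The count with no filter was 8, of which 5 were among the 126. In that fit 4871 probe sets have 6 identical values, against 4 in the filtered fit, and the prior degrees of freedom of the variance model were 0.39 there and 3.14 in the filtered fit. The floor at the 20th percentile moved 0 values, because more of each array already lies at the lowest value, and tests nothing. The replicate block changed no call of a gene list. The cell wall list had a mean of -0.49 (camera adjusted p = 0.0419; adjusted p = 0.268 with an estimated correlation) with the 25S covariate and from -0.52 to -0.27 when 1 array was left out. The mesophyll marker list had a mean of -0.38 (camera adjusted p = 0.0419; adjusted p = 0.268 with an estimated correlation) with the covariate and from -0.43 to -0.080 when 1 array was left out. At the preset correlation both passed with the covariate and without wild type replicate 3, and in no other alternative, and the cause was not tested. Without wild type replicate 3 the adjusted p was 0.32 and 0.376 with an estimated correlation, so neither pass held. RTE1 was called with the 60th percentile filter (limma adjusted p = 0.0478). The actin and microtubule list passed in no alternative (adjusted p from 0.0813 to 0.521), and its mean ranged from 0.091 to 0.22 when 1 array was left out.

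Among the single genes and probe sets named, directions reversed for listed genes that were not called, and the cause was not tested. The mean of the plastid-encoded probe sets turned from 0.10 to -0.18 with the 25S covariate. WSD1 was 0.012 with a common median, UGT74B1 was 0.10 with array weights and 0.023 with the 25S covariate, PRK was -0.0081 and -0.095 in those fits, RCA was -0.046 and -0.069 in them, and SBPASE was -0.15 with the covariate. When 1 array was left out, the log2 change ranged from -0.13 to 0.30 for SIM, -0.39 to 0.092 for MCM7, -0.49 to 0.45 for WSD1, -0.35 to 0.084 for UGT78D1, -0.23 to 0.021 for UGT78D2 and -0.16 to 0.13 for UGT74B1. It ranged from -0.059 to 0.53 for OPCL1, -0.53 to 0.019 for SAG101, -0.39 to 0.14 for WRKY53, -0.083 to 0.28 for EIN3, -0.044 to 0.061 for GT-1, -0.16 to 0.24 for PRK, -0.18 to 0.26 for SBPASE, -0.14 to 0.15 for RCA and -0.032 to 0.54 for FMA. Of the 33 other listed genes named, which kept their sign, 22 moved by over 1.5 times when 1 array was left out, with ranges from -1.89 to -0.93 for XTH18, 0.00049 to 2.09 for PDF1.2, -1.54 to -0.57 for TRY and 0.38 to 1.16 for GRX480. The alternatives for the levels of GTL1 and CCS52A1 were not run, as the annotation assigned them 0 probe sets. Signal limits the dim genes: in 10 of the 126 calls the lower genotype lay within 0.5 log2 units of the floor. That margin leaves out other dim genes, such as AT5G66150 and COR15A, whose lower mean lay below the 40th percentile of every array.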

Other observations

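The count over other splits of the arrays and the fit with the 25S covariate were tests chosen after the main result was seen, and the genes named in the next paragraph were chosen after their values were seen.

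Beyond the genes named so far, 38 called probe sets name 1 gene. The genes described here were picked from these 38 and not by the size of their change. AT3G07000 rose by 2.51, more than any of those picked, from a wild-type mean within 0.5 log2 units of the floor. AT5G33370, a GDSL-type enzyme of cutin synthesis, rose by 1.05 ± 0.16 (log2 change ± SE, n = 3 per genotype), from 12.49 ± 0.21 to 13.54 ± 0.16 (mean ± SD). AT5G12420, of the wax ester synthase family, rose by 2.13 ± 0.14, and AT5G55380, of another wax synthase family, by 1.14 ± 0.17. AT1G62760, of the pectin methylesterase inhibitor superfamily, rose by 2.45 ± 0.13, from 9.16 ± 0.07 to 11.61 ± 0.14, and AT1G68470, of the exostosin family, by 1.31 ± 0.17. GAUT15, a galacturonosyltransferase-family protein of pectin synthesis, fell by 1.3 ± 0.19. AT3G29410, of the terpene synthase family, rose by 1.85 ± 0.15, HMT-1, a homocysteine methyltransferase, by 1.33 ± 0.19 and LPR2, a multicopper oxidase linked to low phosphate in roots, by 1.23 ± 0.14. The cytochrome P450 gene CYP71B29 fell by 1.34 ± 0.15. None of the 38 changed direction in any fit, 14 were called with the replicate block and 1 with no filter, and when 1 array was left out between 6 (without gtl1-1 mutant replicate 3) and 16 (without wild type replicate 3) were called. No enrichment of a function was tested among them, and no shared function can be read from the genes picked.

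The 126 calls between the genotypes were set against technical explanations and against the genotype itself. With the 25S value as a covariate, the median ratio of the log2 changes with and without it was 1.00 over the 126 (quartiles 0.973 and 1.04), 126 kept their sign and 85 stayed called. The covariate moved the called probe sets by a median of 0.049 log2 units and the other tested ones by 0.054. This cannot decide on ribosomal RNA carry-over. The calls were picked from these data for small scatter within genotypes, and the 25S value varied mostly within genotypes. RNA integrity was not tested by that fit and stays open, with a gap of -0.25 between genotypes in the actin control (exact permutation p = 0.3). A different share of photosynthetic leaf cells cannot be told apart from the genotype. The 5 markers did not move together (3 positive, 2 negative), with a mean change of -0.26 and a median of 0.01. Their wild-type mean of 12.29 would hide a small share. The real split gave 126 calls and the highest of the 9 others 0, with 2045 probe sets at an unadjusted limma p under 0.05 against 125 to 1073. Each other split mixes the genotypes, so a difference between them widens the spread within its groups and lowers its counts. Those counts are therefore not the level that chance alone would give. Also, 10 splits are too few for a share under 0.05 (1 of 10 gave as many calls). Among the 4 splits that part all 3 numbered pairs the highest other was also 0, and the genotype stays among the open explanations.

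A hypothesis that called genes lie in chromosomal clusters was tested on gene order. Of 58 called genes, 0 had another called gene within 5 gene positions, where 10000 random draws of tested genes gave a median of 0 and a 95th percentile of 4 (one-sided permutation p = 1). This shows no excess of neighbours among the genes that the annotation names. It cannot exclude clusters, as random draws typically gave 0 too. The 63 unnamed calls had no place in the gene order and could not count.

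A hypothesis that genes sharing a symbol stem shift together was tested on 15 families of at least 8 tested genes. Camera passed 0 of them, and the question stays open because fry passed 1, the CYP stem. It had 9 members (3 positive, 6 negative, 1 called), a mean of -0.33, a fry adjusted p of 0.012 and camera adjusted p of 0.676 (adjusted p = 0.903 with an estimated correlation). Fry does not compare the stem with other genes, and a few members can carry it, so its pass does not show a shared shift. In it CYP71B29, CYP71B26 and CYP71B28 stood at -1.34, -1.63 and -0.49, while CYP71B22 and CYP71B6 stood at 0.56 and 0.40. The stem also takes in CYP71 (AT3G44600) and CYP59, which are cyclophilins and not cytochromes, at -0.13 and -0.07. In the IQD stem, 9 of 11 members had positive changes, also with another quantile normalisation or a common median, although IQD15 fell by 3.1, and the stem passed neither test (camera adjusted p = 0.839, fry adjusted p = 0.783).

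A hypothesis that transcripts of the plastid genome shift between genotypes was tested on 60 probe sets. Their mean change was 0.10 (95% interval over arrays from -1.13 to 1.32), limma called 0 of them (1 at an unadjusted p under 0.05), and neither fry (p = 0.934) nor camera (p = 0.661; p = 0.94 with an estimated correlation) passed. A bound on p was a poor criterion for its absence, as that interval leaves room for a shift of over 1 log2 unit either way. Of the 60, 47 had an unadjusted limma p under 0.05 for the 25S value in the fit that held it, against 1806 of all 13682 tested probe sets. The median slope of the 60 was 0.35 log2 units per log2 unit of 25S, although 0 were called for it. In that fit, added after the data were seen, the mean genotype change turned to -0.18 (median -0.15), and camera passed at the preset correlation (p = 0.00374) but not with an estimated correlation (p = 0.542), nor did fry (p = 0.457).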
